A study of Mus musculus with 6 samples.

How the data were processed

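RNA from glomeruli isolated with magnetic beads was hybridised to Affymetrix arrays, 1 array per mouse, from 3 mice with podocyte-specific deletion of Vhl and 3 wild-type littermates, which the labels call biological replicates. All mice were female and 6 weeks old, per the labels. The groups were taken from the labels alone.

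The deposited values are intensities, 1 MAS5 signal per probe set and array on a linear scale, and the submitters' processing notes name MAS5 without a version. The values show that each array had been scaled so that its mean, without the lowest and highest 2% of values, is 500. Detection calls were not used here. No pair of arrays held identical values, and no array was left out. The ratios of 3′ to 5′ control probe sets, which reflect RNA quality, lay between 0.773 and 0.829 for Gapdh and between 1.30 and 1.38 for actin over the 6 arrays.

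The table has 45101 probe sets, of which 64 are controls. Gene names came from the array's annotation table, checked through Entrez numbers in a RefSeq gene table of the mouse, used for names only. Of the other probe sets, 34945 had 1 symbol, 932 several and 9160 none, and 34741 of those with 1 symbol were matched by number. Probe sets with several symbols or none were left out of the gene test. No genome coordinates were used.

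Values were taken as log2(signal + 28), where 28 is the 25th percentile of all values. This pseudocount makes changes of dim genes smaller than the ratio of their signals. Probe sets in the upper 50% by mean over all 6 arrays were kept, which corresponds to a signal of about 96, and the brightest kept probe set stood for each gene. This left 11159 genes, 5205 of them with several kept probe sets. Among the named genes, Fabp4, Col4a4, Col4a5, Xist and Xaf1 had another kept probe set with a change of opposite sign, and none of these genes passed the threshold.

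Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 7.08 degrees of freedom in all) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p of a gene is from limma. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 19 lists with at least 5 tested members of 21 lists fixed; camera asks whether the genes of a list rank above or below other genes. The lists were also tested with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance. The erythroid list and the list of Y-linked genes with Xist were too small for a set test. The lists hold 488 different genes in all, each counted once, of which 409 were tested. Members were counted over all genes and adjusted over the list alone.

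The lists, the tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule names Vhl, the 12 genes with the largest rise and the 12 with the largest fall among those that passed without overlap of the groups (filled up by lowest unadjusted p, passing over genes without a proper name), from each list the members that passed or else the 3 of lowest p, and a set of glomerular genes. Sequence identifiers such as AA467197 were passed over too, although the rule as written spoke only of Riken, LOC and Gm entries, and AA467197 and Gm266 are given all the same. Other genes outside the rule are given as chosen after their values were seen.

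On simulated data for this comparison with 11159 genes and 200 changed genes in each of 5 runs, the test called 20.3% of genes changed 1.5-fold, 51.6% of those changed 2-fold and 86.4% of those changed 4-fold, and 4.7% of the calls were false. A list of 30 genes shifted by 0.3 was called in 5 of 5 runs and an unshifted list in 0 of 5. The simulated genes varied independently of each other, so these runs do not test lists whose genes vary together between arrays. In the real arrays the estimated correlation ran from -0.0076 (interstitial matrix and fibrosis genes) to 0.89 (mitochondrial respiration). Alternatives changed the scaling of arrays, the pseudocount, the filter, the probe set that stands for a gene, the variance model, array weights, the replicate number as a block, the tubule list mean of each array as a covariate, the threshold and the set test, and left out each array in turn. The covariate together with an estimated correlation was added after the data were seen.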

Results

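The data were Affymetrix expression arrays of glomeruli, the filtering units of the kidney, from 6 female mice aged 6 weeks. In 3 mice a Cre recombinase active in podocytes, the epithelial cells that cover the glomerular capillaries, had deleted a floxed Vhl gene, and 3 wild-type littermates were the controls. Vhl encodes the part of a ubiquitin ligase that marks the hypoxia-inducible factors (HIF) for degradation. The Vhl-deleted mice had been selected for urinary albumin no higher than the wild-type mean, measured at 4 weeks. Each mouse gave 1 array of 45101 probe sets. The 2% trimmed mean was 500 in all 6 arrays and the median signal lay between 94.6 and 107.5, and the number of arrays limits the precision of every value. Changes are log2 differences, Vhl-deleted minus wild-type, of signal + 28, with the standard error (SE), and n = 3 arrays per group throughout.

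The comparison asked which transcripts of the glomerulus differed when podocytes lacked Vhl in mice selected as above; albumin at 6 weeks, when the arrays were made, is not given in the sources used here. Egln3, a prolyl hydroxylase of HIF that is itself a HIF target, was 24.8-fold higher, and Ngb, which encodes the oxygen-binding protein neuroglobin, was 11.0-fold higher. Enzymes and transporters of glycolysis were higher as a list, by a median of 0.62 on the log2 scale (camera adjusted p = 1.89e-18, and adjusted p = 0.0863 with an estimated correlation). Of 11159 genes tested, 8 rose and 1 fell in the Vhl-deleted glomeruli. Vhl itself had a mean signal of 727 ± 74.1 (SD, n = 3) in wild-type and 612 ± 6.46 (SD, n = 3) in Vhl-deleted arrays, a log2 change of -0.23 (95% interval -0.51 to 0.04) with an adjusted p of 0.944. Its 3 Vhl-deleted arrays all lay below the 3 wild-type arrays. The other Vhl probe set changed by -0.17. Glomerular cells other than podocytes keep Vhl, and whether the probes lie in the deleted part is not given in the sources used here, so this is a limited check of the labels.

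The 8 genes that rose were Egln3, Ngb, Zbtb8b, Ppp1r3c, Pcsk6, Pfkl, Bsg and Pkm. The Egln3 signal (probe set 1418649_at) went from 154 ± 14.6 to 4523 ± 747 (SD), a log2 change of 4.63 (SE 0.15, adjusted p = 9.74e-05). The Ngb signal (1417996_at) went from 235 ± 75.1 to 2821 ± 365 (SD), a log2 change of 3.46 (SE 0.22, adjusted p = 0.00308). The second probe sets of these genes moved by 4.83 and 3.50. Zbtb8b, a zinc finger protein gene, had a signal of 34.1 ± 9.73 in wild-type and 577 ± 106 (SD) in Vhl-deleted arrays, a change of 3.28 (adjusted p = 0.00308), and its wild-type level was near the pseudocount, so this value understates the ratio of the signals. Ppp1r3c, a glycogen-targeting subunit of a protein phosphatase, rose by 2.28 (SE 0.24, adjusted p = 0.0354). Pcsk6, a proprotein convertase, rose by 2.24 (SE 0.16, adjusted p = 0.00595). Bsg encodes basigin, a partner of the monocarboxylate transporters, and rose by 1.06 (SE 0.11, adjusted p = 0.0354). Slc26a7, an anion transporter gene, was the gene that fell, from a signal of 3331 ± 331 to 1441 ± 177 (SD), a log2 change of -1.20 (adjusted p = 0.0450). In each of the 9 genes the 3 arrays of one group lay beyond the 3 of the other. Over all genes tested this held for 10.7%, where chance gives 10%.

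**Figure D1:**
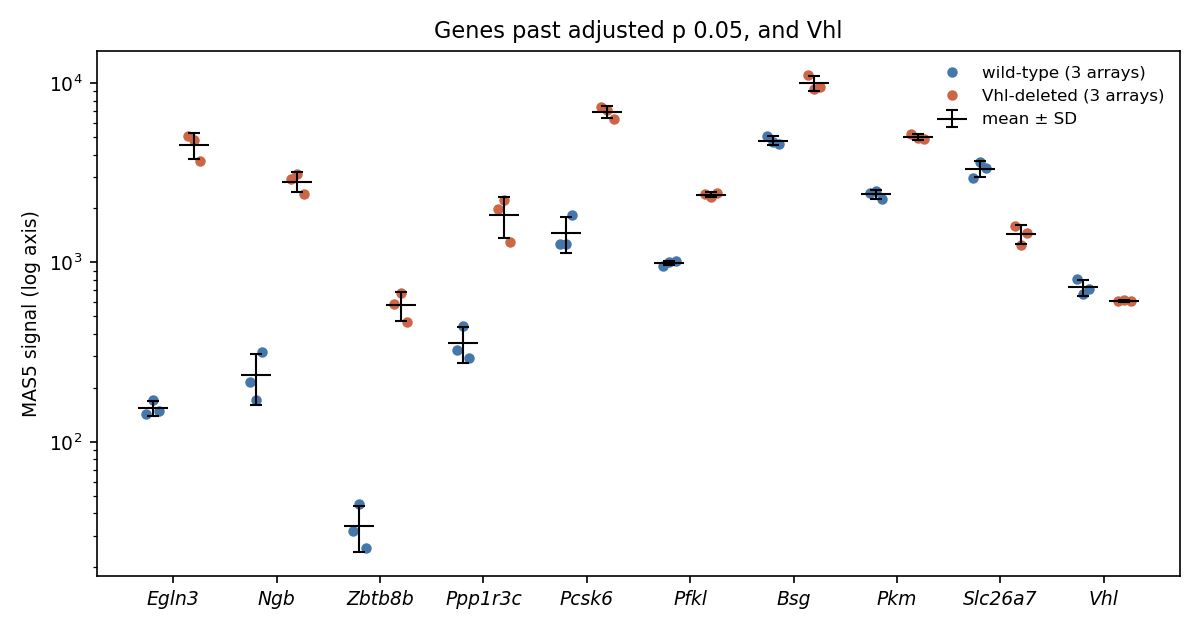
MAS5 signal on a log axis of the 9 genes past the adjusted p threshold of 0.05 and of Vhl. Points are arrays, 3 wild-type (blue) and 3 Vhl-deleted (red), and black marks are the mean ± SD. The Egln3 mean goes from 154 to 4523 and the Vhl mean from 727 to 612.

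Several genes came close to the threshold without passing it. The nearest was AA467197, a gene known by a sequence identifier, at 19.2 ± 23.9 in wild-type and 338 ± 42.1 (SD) in Vhl-deleted arrays, a log2 change of 3.06 with an adjusted p of 0.0503, which passed with quantile normalization, median scaling, robust variance, array weights and the tubule covariate, among others. Mki67, a marker of proliferating cells, was at 209 ± 9.36 in wild-type and 451 ± 4.89 (SD) in Vhl-deleted arrays, with an adjusted p of 0.0518. Efhd1, a mitochondrial calcium-binding protein gene, had a log2 change of 2.37, and the kinase gene Stk17b of 1.34, both with an adjusted p of 0.0518. The fatty acid binding protein gene Fabp5 was at 1.33 and the chloride channel protein gene Clic3 at -0.73, both with an adjusted p of 0.0746. In the lower direction, Gm266, a predicted gene, was at -1.27 (adjusted p = 0.0900). Among the other genes of lowest p in that direction were the chemokine receptor gene Ackr3 at -0.54 (adjusted p = 0.268), the growth factor gene Pdgfc at -0.58 (adjusted p = 0.347) and the transporter gene Slc10a6 at -1.62 (adjusted p = 0.535). Others of that group (Abca5, Samd5, Ephb1, Ppwd1, Noct and Siva1) had changes between -0.54 and -0.99, and none of them passed.

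Of the HIF glycolysis list, 17 of 18 tested members had a positive change. Over all genes tested, 2 of them rose, and 11 rose when adjusted over the list alone. The phosphofructokinase gene Pfkl rose by 1.24 (SE 0.09, adjusted p = 0.00595) and the pyruvate kinase gene Pkm by 1.05 (SE 0.09, adjusted p = 0.0172). The glucose transporter gene Slc2a1 had a change of 0.76 (adjusted p = 0.268 over all genes, 0.00325 over the list alone). Lactate dehydrogenase A (Ldha, 0.93) and triosephosphate isomerase (Tpi1, 1.07), chosen after their values were seen, passed over the list alone with adjusted p of 0.00145 and 0.00419. With the tubule covariate these genes also passed over all genes (limma adjusted p = 0.011 each). The list ranked above other genes with an adjusted p of 1.89e-18 by camera, and with adjusted p = 0.0863 with an estimated correlation. Its mean level was 9.68 in wild-type replicate 3, against 9.99 and 10.06 in the other wild-type arrays and 10.45 to 10.56 in the Vhl-deleted arrays.

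Of the HIF targets other than glycolysis, 39 were tested and 29 had a positive change, with a median of 0.31. Egln3 and Ngb rose over all genes. Adjusted over the list alone, 9 rose and 1 fell. The mitophagy receptor gene Bnip3 (1.23), the collagen lysyl hydroxylase gene Plod2 (0.81) and the adrenomedullin gene Adm (1.15) were among the 9, and Tgfa (-0.45), a ligand of the epidermal growth factor receptor, was the one that fell; these 4 were chosen after their values were seen. Vegfa, the vascular endothelial growth factor that podocytes make, had a change of 0.42 (95% interval 0.10 to 0.74) with an adjusted p of 0.851, and did not pass over the list alone either (0.0585). The list was shifted up with an adjusted p of 2.36e-10, and with adjusted p = 0.0361 with an estimated correlation. Without wild-type replicate 3 its median was 0.19, still shifted. With the tubule covariate Bnip3, Plod2 and Adm also passed over all genes (limma adjusted p = 0.0032, 0.024 and 0.0067). The angiogenic signalling list, 8 of whose 22 genes stand in another list too, had a median of 0.14 (adjusted p = 0.00422, and adjusted p = 0.141 with an estimated correlation), and 0 of its 19 tested members passed over all genes or adjusted over the list alone. Without wild-type replicate 1 its median was 0.08 and the call was lost (adjusted p = 0.0693), and its median was also 0.08 with median scaling. Vegfc was at 0.59 and the receptor gene Kdr at 0.28. Cxcr4, a chemokine receptor gene named before the data were examined, was at 0.14 (95% interval -0.22 to 0.50).

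**Figure D2:**
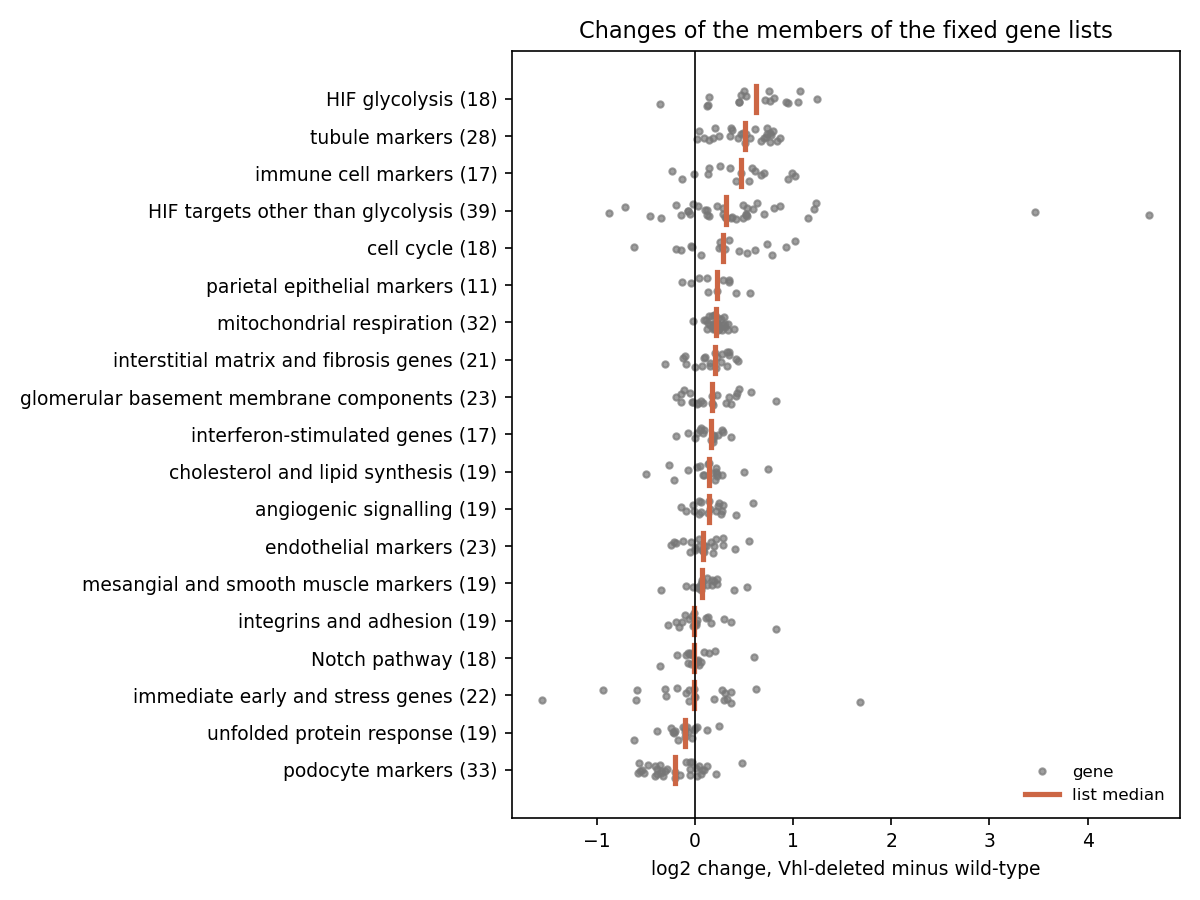
Log2 change (Vhl-deleted minus wild-type) of each tested member of 19 gene lists, with the number of tested genes in brackets. Grey points are genes and red bars are list medians. The HIF glycolysis median is 0.62 and the podocyte median -0.21.

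Podocyte markers lay lower and tubule markers higher in the Vhl-deleted arrays as lists, with no member past the threshold in either. Of 33 podocyte markers tested, 24 had a negative change, with a median of -0.21, and 0 passed over all genes or adjusted over the list alone. The nephrin gene Nphs1 was at -0.38, the transcription factor genes Wt1 and Lmx1b at -0.34 and -0.53, and Cdkn1c, a cell cycle inhibitor of mature podocytes, at 0.48. All 28 tubule markers had a positive change, with a median of 0.51, and 0 passed over all genes or over the list alone. Lrp2, the megalin gene of the proximal tubule, had a signal of 4131 ± 2721 in wild-type and 5396 ± 768 (SD) in Vhl-deleted arrays, and Fbp1 and Kap were at 0.87 and 0.73. The tubule list mean was 10.44 in wild-type replicate 3, against 12.003 and 12.28 in wild-type replicates 1 and 2 and 11.86, 11.77 and 12.59 in Vhl-deleted replicates 1, 2 and 3. The podocyte list mean was 12.56 in wild-type replicate 3, against 12.21 and 12.15 in the other wild-type arrays. The camera adjusted p was 6.1e-05 for the podocyte list and 0.000113 for the tubule list, and adjusted p = 0.577 with an estimated correlation for each. Without wild-type replicate 3 the podocyte median was -0.11 (adjusted p = 0.0556) and the tubule median -0.04 (adjusted p = 0.449). Without Vhl-deleted replicate 3 both calls were lost as well (medians -0.14 and 0.29), and with array weights (medians -0.07 and -0.02), and without wild-type replicates 1 or 2 the tubule median was 0.79 or 0.94.

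Among the markers of other glomerular cells, the 23 endothelial markers tested had a median of 0.08 (adjusted p = 0.0491) and the 19 mesangial and smooth muscle markers one of 0.08 (adjusted p = 0.0159). The 11 parietal epithelial markers had a median of 0.22 (adjusted p = 0.0304). With an estimated correlation these were adjusted p = 0.577, adjusted p = 0.577 and adjusted p = 0.525, and 0 members of these 3 lists passed over all genes or adjusted over the list alone. Fabp4 and Cd34 were at 0.41 and 0.29, Pecam1 at -0.21, Myl9 at 0.40 and Pdgfrb at 0.22. The endothelial call was lost with quantile normalization and median scaling among others, and without wild-type replicate 1, wild-type replicate 2, Vhl-deleted replicate 1 or Vhl-deleted replicate 2 (medians 0.02, 0.08, 0.07 and 0.05), while the median was 0.19 without wild-type replicate 3 (adjusted p = 2.52e-05), 0.14 without Vhl-deleted replicate 3 (adjusted p = 0.000457) and 0.18 with the tubule covariate (adjusted p = 1.12e-05, and adjusted p = 0.0686 with an estimated correlation), shifted in each; the mesangial call was lost with quantile normalization and without wild-type replicate 1 (0.00) or Vhl-deleted replicate 3 (0.09), and its median was 0.19 without wild-type replicate 3, 0.12 without wild-type replicate 2, 0.16 without Vhl-deleted replicate 1 and 0.16 with the tubule covariate (adjusted p = 0.336 with an estimated correlation), shifted in each. The parietal call was lost in 10 of 21 settings, among them with the tubule covariate (median -0.01, adjusted p = 0.296) and without wild-type replicate 3 (-0.06, adjusted p = 0.495), Vhl-deleted replicate 1 (adjusted p = 0.0944) or Vhl-deleted replicate 3 (adjusted p = 0.106). The parietal list includes Vcam1 (0.57) and Cd44 (0.35), and its mean was 8.82 in wild-type replicate 3 against 9.32 and 9.44 in the other wild-type arrays.

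**Figure D3:**
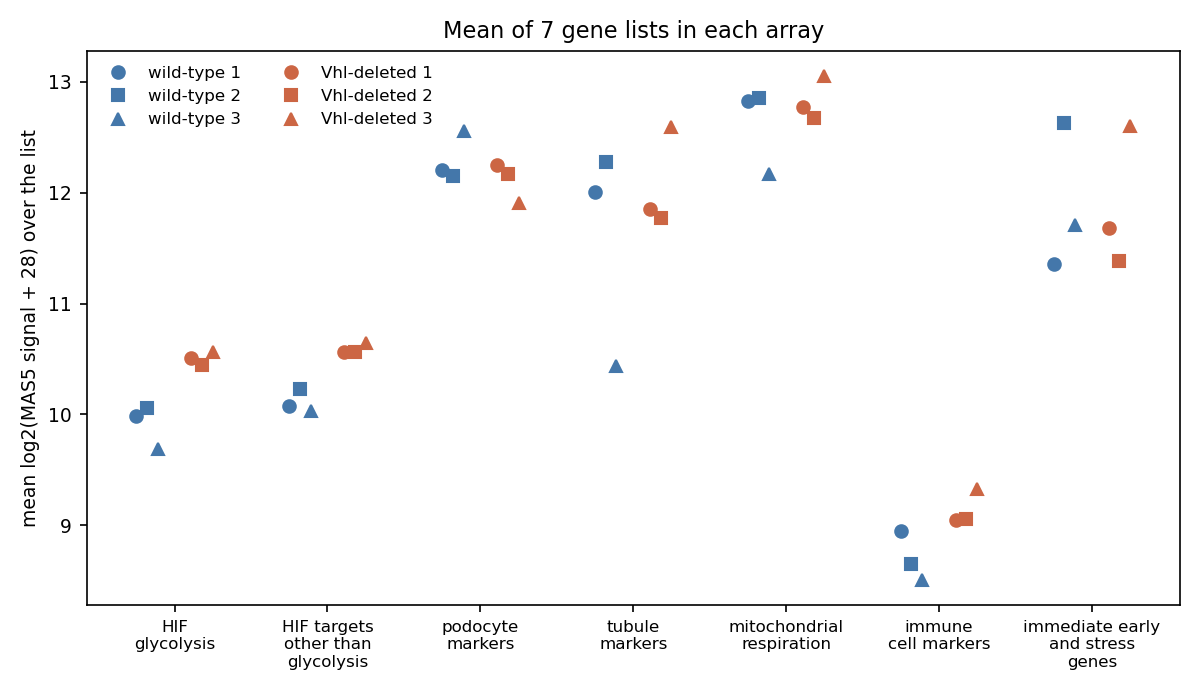
Mean log2(MAS5 signal + 28) of 7 gene lists in each of the 6 arrays. Blue symbols are wild-type and red symbols Vhl-deleted arrays, and the shape gives the replicate. Wild-type replicate 3 has a tubule mean of 10.44, below the other 5 arrays at 11.77 to 12.59.

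Components of the glomerular basement membrane, the extracellular sheet between podocytes and endothelium, had a median change of 0.17 over 23 genes. None passed over all genes, and the laminin gene Lamb1 (0.57, SE 0.11) rose when adjusted over the list alone (adjusted p = 0.0294). The collagen IV genes differed in size: Col4a1 was at 0.42 (95% interval 0.05 to 0.79), Col4a2 at 0.37 (0.11 to 0.63) and Col4a6 at 0.82 (0.31 to 1.34), while Col4a3 was at -0.14 (-0.41 to 0.13), Col4a4 at 0.08 (-0.17 to 0.33) and Col4a5 at -0.02 (-0.52 to 0.48). None of these 6 passed over all genes or over the list alone, Col4a4 turned to -0.03 with quantile normalization, and the differences between them were not tested. Without wild-type replicate 3 Col4a4 was at 0.16 and Col4a5 at 0.22, and with the tubule covariate Col4a5 was at 0.18. The list was shifted up with an adjusted p of 0.000867, and with adjusted p = 0.525 with an estimated correlation, and without wild-type replicate 2 the call was lost (median 0.06, adjusted p = 0.0786). Without Vhl-deleted replicate 1 its median was 0.08 and the call held. Interstitial matrix and fibrosis genes had a median of 0.21 over 21 genes (adjusted p = 0.000204, and adjusted p = 0.0863 with an estimated correlation), a median of 0.13 without wild-type replicate 3, with Bgn at 0.42, Mmp2 at 0.44 and 0 past the threshold over all genes or adjusted over the list alone. Integrins and adhesion genes had a median of -0.00 and a mean of 0.05 (adjusted p = 0.598; 0.00708 without wild-type replicate 3 and 0.0111 with the tubule covariate, and past the threshold with array weights too; adjusted p = 0.869 with an estimated correlation, and adjusted p = 0.136 with an estimated correlation and the covariate), with Itga2 at 0.83 and Zyx at 0.37.

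Immune cell markers had a median change of 0.47 over 17 genes. Over all genes 0 passed, and adjusted over the list alone 5 rose: the MHC class II genes H2-Eb1 (0.99), H2-Aa (0.94) and H2-Ab1 (0.71), their invariant chain Cd74 (1.02) and the leukocyte antigen gene Ptprc (0.67). H2-Ab1 and Ptprc were chosen after their values were seen. The camera adjusted p was 5.25e-08, and adjusted p = 0.177 with an estimated correlation. The list mean was 8.95, 8.65 and 8.50 in wild-type and 9.05, 9.05 and 9.32 in Vhl-deleted replicates 1 to 3. Cell cycle genes had a median of 0.29 over 18 genes (adjusted p = 1.34e-05, and adjusted p = 0.141 with an estimated correlation), and 4 rose when adjusted over the list alone: Mki67 (1.02), Ccnb2 (0.61), Ccna2 (0.73) and Top2a (0.78), the last chosen after its value was seen. Over all genes 0 of them passed. Among the brightest 30% of probe sets the cell cycle list was no longer shifted, and the lowest of its medians over the 21 settings was 0.02.

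The immediate early and stress list was not shifted (median -0.01, adjusted p = 0.211), but was shifted down without wild-type replicate 1, wild-type replicate 3 or Vhl-deleted replicate 3 (medians -0.19, -0.17 and -0.38), with the tubule covariate (median -0.255, adjusted p = 0.004445, and adjusted p = 0.590 with an estimated correlation) and with array weights; without the covariate it had adjusted p = 0.798 with an estimated correlation. Adjusted over the list alone, the heat shock genes Dnajb1 (-0.59), Hspa1b (-0.93) and Hspa1a (-1.55) fell, and over all genes 0 members passed. The mean of this list was 12.63 in wild-type replicate 2 and 12.60 in Vhl-deleted replicate 3, against 11.36 to 11.71 in the other 4 arrays. Mitochondrial respiration genes had a median of 0.22 over 32 genes, 31 of them positive (adjusted p = 1.83e-05, and adjusted p = 0.577 with an estimated correlation), with Cox5a at 0.34 and 0 past the threshold over all genes or adjusted over the list alone. Their mean was 12.17 in wild-type replicate 3, against 12.83 and 12.86 in the other wild-type arrays, and without that array the median was 0.00 (adjusted p = 0.950); the call was also lost with the tubule covariate (0.03, adjusted p = 0.240) and with array weights (0.01), while the median was 0.35 without wild-type replicate 2 and 0.13 without Vhl-deleted replicate 3, shifted in each. The unfolded protein response list had a median of -0.10 (Dnajb9 at -0.24) and the cholesterol and lipid synthesis list one of 0.14 (Sqle at 0.75), each with an adjusted p of 0.0411, and with adjusted p = 0.606 and adjusted p = 0.525 with an estimated correlation. The unfolded protein response call was lost without wild-type replicate 3 or Vhl-deleted replicate 3 (medians 0.02 and 0.00), with the tubule covariate (0.01, adjusted p = 0.794), with array weights (0.05) and with no intensity trend, its median was -0.19 without wild-type replicate 1 and -0.16 without Vhl-deleted replicate 2, and the cholesterol call was lost with array weights, with the mean over probe sets and without wild-type replicate 2 (0.03), Vhl-deleted replicate 1 (0.11) or Vhl-deleted replicate 3 (0.14). Interferon-stimulated genes (median 0.17, adjusted p = 0.121) and the Notch pathway (median -0.01, mean 0.02, adjusted p = 0.838) were not shifted, although the interferon list was without wild-type replicate 3 or Vhl-deleted replicate 1 (medians 0.20 and 0.27) and with the replicate block (adjusted p = 0.733 with an estimated correlation), with Rsad2 at 0.29 and Hey2 at 0.61. In these last 4 lists 0 members passed over all genes or adjusted over the list alone. The erythroid list had 3 tested genes, too few for a set test, with Alas2 at -0.40. Xist was at 11382 ± 1082 in wild-type and 13044 ± 1583 (SD) in Vhl-deleted arrays, and the Y-linked genes with a probe set were under the filter.

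Of the 19 lists tested, camera with its preset correlation called 15 shifted, 13 up and 2 down. With an estimated correlation 1 remained past the threshold, the HIF targets other than glycolysis. With fry 4 passed, all up: both HIF lists, the cell cycle list and the interstitial matrix list. The camera p also rose in lists whose estimated correlation lay below the preset 0.01. In the HIF targets other than glycolysis (0.0043) the unadjusted camera p went from 2.48e-11 to 0.0019. In the interstitial matrix list (-0.0076) it went from 8.59e-05 to 0.0126. Correlation between genes is therefore not the whole reason why calls were lost in this setting. In single genes, 280 were higher and 269 lower at an unadjusted p under 0.05, where chance gives 558 in all. The counts of 8 higher and 1 lower became 11 and 0 when arrays were scaled by their median. Leaving out an array moved the count of genes that rose to 5 without wild-type replicate 2, 13 without wild-type replicate 3, 1 (Egln3) without Vhl-deleted replicate 1 and 3 without Vhl-deleted replicate 2, and Slc26a7 kept its call in 9 of 19 settings.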

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

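The tests of Prm1 were chosen after its values were seen. A probe set with no gene symbol (1440645_at), outside the gene test, went from a signal of 26.9 ± 18.2 in wild-type to 2216 ± 421 (SD) in Vhl-deleted arrays, a log2 change of 5.397 (limma adjusted p = 0.00113 with every kept probe set tested on its own). Also outside the gene test, 2 probe sets of the protamine gene Prm1 (1437054_x_at and 1439379_x_at), which in adults is known from sperm heads, had changes of 4.298 and 4.352 (adjusted p = 0.0116 and 0.0236 over all kept probe sets). These are the probe sets past the threshold that stand for no gene of the comparison and whose gene did not pass there.

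The Prm1 signals were 1.90 ± 1.02 and 4.05 ± 5.23 in wild-type and 617 ± 336 and 703 ± 413 (SD) in Vhl-deleted arrays, and the probe set that stood for Prm1 changed by 1.13 (adjusted p = 0.815). Without wild-type replicate 3, Prm1 passed in the gene test, where the probe set that stands for a gene is chosen anew. RNA of male germ cells is argued against, because the 4 probe sets of Prm2, Tnp1 and Tnp2, genes of the same cells, had a median change of -0.174. A candidate explanation is a transcript of the Cre transgene, since such transgenes can carry Prm1 sequence. The 3 Prm1 probe sets were higher in every Vhl-deleted array than in every wild-type array (3 of 3), but the transgene sequence was not used here and the transgene and the Vhl deletion occur in the same mice, so these cannot be told apart.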

How the results depend on the processing

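The covariate joined with an estimated correlation was chosen after seeing the data. Egln3 kept its call in 19 of 19 settings (adjusted p 3.33e-06 to 0.0197), Ngb in 17, Pcsk6 in 16, Pfkl in 14, Pkm and Ppp1r3c in 13, Bsg in 12 and Slc26a7 in 9 of 19, and Zbtb8b in 16 of 18; Pkm and Bsg lost it in 5 of the 6 settings with an array left out, and Slc26a7 in all 6. With every probe set tested on its own, 14 probe sets rose, which stand for 9 genes of the comparison, Prm1 (2 probe sets) and a probe set with no symbol. The count of genes that rose (8) was 30 with array weights, 31 with the tubule covariate, 92 at an unadjusted p under 0.01, and 1 to 13 when an array was left out. The count that fell (1) was 0 with median scaling, the mean over probe sets or no intensity trend, 3 with array weights, 4 with the tubule covariate, 58 at an unadjusted p under 0.01, and 0 to 1 when an array was left out. At an unadjusted p under 0.01 chance gives 112 genes in all, so most of the 92 and 58 may be chance. No label says that a shared replicate number marks a litter or day. Correlations of deviations between arrays of the same number were -0.02, -0.41 and -0.51, and 0 of 6 arrays correlated best with their own number. These values show no pairing but cannot exclude one, because the largest variation between arrays followed the tubule mean. With the replicate block 1 gene rose (Egln3), 0 fell and 15 lists were shifted. Of lists, 1 was shifted with an estimated correlation, 4 by fry and 0 with the covariate and an estimated correlation, where the HIF glycolysis list (median 0.5027) and the other HIF targets (0.2149) had adjusted p = 0.0575 each; the HIF glycolysis list (0.6182) had 0.0863 with the estimated correlation alone. Values that turned direction (for lists, that of camera), none of them past the threshold there: with array weights the medians of the tubule (-0.0209), mitochondrial (0.01013) and unfolded protein response (0.04657) lists, Slc4a1 (-0.1332), Bpgm (-0.07647), Psmb8 (-0.1408) and Col4a5 (0.2241); with the tubule covariate Slc4a1 (-0.12), Bpgm (-0.06939) and Col4a5 (0.1825); with quantile normalization Slc4a1 (-0.02185) and Col4a4 (-0.02653); with median scaling Slc4a1 (-0.03199) and Bpgm (-0.05763); with the mean over probe sets Xaf1 (-0.03406), Xist (-0.03246) and Col4a5 (0.03419). List medians that changed sign while camera's direction held were, with the tubule covariate, parietal (-0.006521), unfolded protein response (0.01331), integrins (0.0789) and Notch (0.07013), with array weights integrins (0.09197) and Notch (0.06274), with the mean over probe sets integrins (0.01436) and Notch (0.007334), and with no filter Notch (0.01506); integrins passed with the covariate and with array weights. With an array left out, medians ranged from -0.04031 (without wild-type replicate 3) to 0.9445 for the tubule list, 0.004006 (without wild-type replicate 3) to 0.35 for mitochondrial respiration, -0.0622 to 0.1006 for integrins, -0.05918 to 0.3417 for parietal markers, -0.06473 to 0.09182 for Notch, -0.3752 to 0.498 for the immediate early and stress list, -0.09523 (without Vhl-deleted replicate 3) to 0.2721 for interferon-stimulated genes and -0.189 to 0.01532 for the unfolded protein response, and changes from -0.07869 to 0.05589 for Bpgm, -0.3123 to 0.03277 for Notch4, -0.04066 to 0.5863 for Psmb8, -0.1638 to 0.2185 for Col4a5 and -0.08169 to 1.188 for Lrp2. The cause was not tested, except that leaving out an array or adding a block leaves fewer degrees of freedom. Of the other results, 1800 values for single genes and lists kept their direction and side of the threshold, 112 lost a call and 30 gained it. Most of the kept values belong to genes that had not passed in the main comparison, so they say little about how stable the calls are. Signals near the pseudocount of 28 limit what can be seen of dim genes.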

Other observations

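The tests of tubule content and of blood were chosen after related values had been seen, and so was the rule that a list kept under the covariate counts against tubule content only if its unadjusted p with an estimated correlation was under 0.05; the counts of splits were planned, except that of genes at an unadjusted p under 0.05. The podocyte list was lower (median -0.21) and the mitochondrial list higher (0.22) in the Vhl-deleted arrays, while wild-type replicate 3 had the lowest tubule mean (10.44), and 0 of the 30 tubule genes stand in another list. For the mitochondrial list, the values are consistent with tubule content: its median was 0.004006 without wild-type replicate 3 (adjusted p = 0.950) and 0.03088 with the tubule mean as covariate (adjusted p = 0.240). For the podocyte list the same settings gave -0.1129 (adjusted p = 0.0556) and -0.1266 (adjusted p = 0.0142, and p = 0.316 unadjusted with an estimated correlation). Tubule content and an effect of the deletion cannot be told apart for the podocyte list, because its genes vary together between arrays of a group.

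The immune list (median 0.47) and the cell cycle list (0.29) were higher in the Vhl-deleted arrays. Whether blood left in the glomeruli was a source of the immune markers was examined with 4 erythroid probe sets not near saturation. Their median was -0.196 (SD 0.253). The 4 adult globin probe sets tried before them, 3 of which were among the brightest signals, had a median of -0.0606. A second kept probe set of Slc4a1, not among the 4 erythroid ones, was at 0.62 (SE 0.40), above the immune median of 0.47. The 4 erythroid probe sets showed no rise as a set, but they cannot exclude blood, because the probe sets of Slc4a1 differed. With the tubule mean as covariate the cell cycle median was 0.2456 (camera adjusted p = 7.15e-05). With the covariate and an estimated correlation its camera p was 0.0313 unadjusted and 0.0939 adjusted. The unadjusted value meets the rule given above, but that rule was chosen after related values had been seen. Without wild-type replicate 3 the cell cycle median was 0.1998 (camera adjusted p = 0.000124), where the tubule median was -0.04. The cell cycle mean was 9.38 and 9.48 in Vhl-deleted replicates 1 and 2, against 9.21 and 9.18 in wild-type replicates 1 and 2. The tubule means of these Vhl-deleted arrays (11.86 and 11.77) lay below those of these wild-type arrays (12.003 and 12.28). These values argue against tubule content as the whole cause of the shift in these arrays. A part in it stays open, as the cell cycle list did not pass after adjustment with the covariate and an estimated correlation. The immune median was 0.3324 with the covariate (camera adjusted p = 2.59e-06) and 0.3207 without wild-type replicate 3 (adjusted p = 1.51e-05). Both medians lie below the 0.47 of the main comparison, and the camera call held in both settings. With an estimated correlation the unadjusted camera p of the immune list was 0.0558 without the covariate and 0.0925 with it. As the list did not pass there in either case, these values cannot decide whether tubule content has a part in the immune shift. A change in the cells of the Vhl-deleted glomeruli may also underlie the higher immune and cell cycle lists and was not tested.

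The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05, since the real split alone makes 1 of 10. The real split gave 9 changed genes, and the highest of the others 2. It gave 15 shifted lists against 10, a HIF glycolysis median of 0.62 against 0.35, and a median of the other HIF targets of 0.31 against 0.17. At an unadjusted p under 0.05 the real split gave 549 genes, and 2 others gave more (3 of 10 as large): 648 for wild-type replicates 1 and 3 with Vhl-deleted replicate 2, and 1440 for wild-type replicates 1 and 2 with Vhl-deleted replicate 3. The last points to a structure of the samples other than genotype, and its 3 arrays are those with the highest tubule means (12.003, 12.28 and 12.59). The first principal component, the axis of largest variation between arrays, held 57.5% of the variance. Its correlation with the tubule mean over the arrays was 0.999 in size. Wild-type replicate 3 (46.6) and Vhl-deleted replicate 3 (-27.8) lay at its ends, and it did not separate the groups.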
